A study of Mus musculus with 4 samples.

How the data were processed

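Digital gene expression by SAGE (DGE-SAGE) counts short sequence tags rather than whole transcripts. The cDNA made from poly(A) RNA is cut by the enzyme NlaIII at CATG sites, and the bases next to the site nearest the poly(A) end are sequenced as the tag of that transcript. Per the labels, total RNA came from dissected limbs of CD1 mouse embryos at E14.5. There were 2 limb types, forelimb and hindlimb, each with 2 biological replicates, which made 4 libraries. The labels do not say whether a sample held limbs of 1 or more embryos, nor whether the forelimb and hindlimb of a replicate number came from the same animals, and they give no batch or date.

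The authors deposited 1 table of whole-number tag counts, with a UniGene cluster and an Ensembl gene for each tag where one was assigned. Per the submitters' processing notes, Bowtie and the mouse build mm9 were used; the version and settings are not given in the sources used here. The deposited counts are raw and unnormalized, since the columns sum to different totals. The table held 733961 tags of 17 bases, of which 270911 had no count in any library. An Ensembl gene or a UniGene cluster was given for 166502 tags. Counts of these tags were summed per Ensembl gene, or per UniGene cluster where no Ensembl gene was given, which made 26252 features, 17677 with an Ensembl gene and 8575 with a cluster alone. Tags with neither, 14.8% to 18.7% of the counts of a library, stayed out of library sizes and tests. Symbols were taken from GENCODE M21 by Ensembl identifier and were found for 17004 of the 17677 genes. As a check, each tag was matched to the sense strand of the M21 transcripts next to every CATG. Among tags that matched 1 gene, 99.0% of the counts lay in tags to which the deposited table gave the same gene. Positions are from GENCODE M21 on GRCm38, not from mm9.

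Library totals ran from 1829647 in forelimb replicate 2 to 5325279 in hindlimb replicate 1. In CPM, edgeR's unit of counts scaled by library size, 1 count was worth 0.621 CPM in forelimb replicate 2 and 0.224 to 0.256 CPM in the others. Where a limb type had no count of a gene, a fold was computed against 3 counts over the group and is a lower bound. Tags are PCR products without molecular identifiers, so intervals (Wilson, 95%) and lower bounds cover counting error only.

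Hindlimb was compared with forelimb by edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (glmQLFit, glmQLFTest), TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05, without a block for the replicate number. Log2 fold changes are hindlimb over forelimb, so a negative value is higher in forelimb. CPM values are TMM-scaled and given as mean ± SD with n = 2. The design leaves 2 residual degrees of freedom. The comparison, the 24 gene lists and the rule for named genes were fixed before the data were examined. Named by that rule were Tbx5, Tbx4 and Pitx1; the 8 largest called changes in each direction among genes with separate limb types and a mean of at least 1 CPM; up to 4 called members of each list with the smallest p, or the 2 most abundant members where none was called; and 5 genes for tag usage. Genes named outside the rule were chosen after their values were seen and are marked so.

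The lists were hindlimb identity, forelimb identity, the HoxA, HoxB, HoxC and HoxD clusters, limb patterning and signalling, cartilage, hypertrophic cartilage and growth plate, osteoblast, joint interzone, tendon, skeletal muscle, cell cycle, growth factors and imprinted growth genes, erythroid, endothelium, epidermis, macrophage, Schwann cell and neural crest, neuron, mature adipose and smooth muscle, immediate early and stress, and sex-linked genes. Lists with at least 3 tested members were tested by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), which asks whether a list ranks apart from all other genes, with Benjamini-Hochberg adjustment over the lists. Differing tag usage, a change in the ratio of tags of 1 gene, was tested by diffSpliceDGE in edgeR (Simes, Benjamini-Hochberg over genes). Counts of called members are given over all genes tested and adjusted over the list alone.

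Base composition of the tags differed between the libraries, and 3 corrections were tried in turn, all chosen after the data had been seen. The first was an offset per library from a lowess (span 0.3) of log2 CPM deviations on the GC percent of a gene's tags. The second added a term for G or C as the first base. The third, called here the tag-sequence offset, was built after effects of single positions had been seen. It models base and position over the 17 bases, the first dinucleotide and quadratic terms of GC and purine number, and is fitted per library only on differences between tags of the same gene, so that a difference in the level of a whole gene cannot enter the fit. Results without an offset remain the main ones, as fixed beforehand, and values with the tag-sequence offset are set beside them. Because edgeR's tag test takes no offset per tag, corrected tag usage used diffSplice on limma-voom values.

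The procedures were tested on simulated data made from the libraries' own means and depths, with 200 changed genes. Spread between replicates was set by 1 biological coefficient of variation for all genes, 0.255, taken from the fit with the GC offset. In the fit without an offset it was 0.299, so the simulation may be optimistic for that fit. For the hindlimb to forelimb comparison without base effects (13202 genes), edgeR recovered 9 of 100 genes changed by 2-fold and 87 of 100 changed by 4-fold, with 7 false calls. With the fitted tag-sequence effects put in (13414 genes), it made 1970 false calls without an offset and 8 with the tag-sequence offset, which recovered 14 of 100 genes changed by 2-fold and 83 of 100 changed by 4-fold. That simulation used the effects the model itself had fitted and is therefore optimistic for the offset. In the tag usage simulation without base effects (8019 genes), edgeR recovered 44 of 193 genes with 1 tag changed by 4-fold, with 3 false calls. With the fitted tag-sequence effects put in (8191 genes), tag usage was run by limma-voom alone. It made 3606 false calls without the tag-sequence model. With the model, again on its own effects, it made 3 and recovered 77 of 195 changed genes.

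Alternatives fixed beforehand were other size factors, no filter and a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, the replicate block, leaving out each library, the most abundant tag of each gene, removal of haemoglobin genes and thresholds of 0.1 and 0.01. For lists they were camera with an estimated correlation and fry, and for tag usage a minimum of 20 counts per tag and the top 2 tags of each gene. Camera with an estimated correlation takes its p from the 2 residual degrees of freedom, which leaves it little power. Chosen after the data had been seen were the 3 offsets, removal of tags with 10 or more bases of adapter, tags of 1 M21 gene, tags at the last NlaIII site, Ensembl genes alone, thinning to the smallest library, a crossed block and, for tag usage, limma-voom. A planned restriction to uniquely matching tags marked in the table was not run, as the table carries no such mark, and planned pseudocounts for normalized values did not apply to counts. Figures were drawn with matplotlib 3.10.9.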

Results

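Tag counts were collected from forelimbs and hindlimbs of CD1 mouse embryos at E14.5, a stage at which cartilage models, muscles and joints of the limb are forming. Each limb type had 2 biological replicates. The total count was 4695786 and 1829647 tags in forelimb replicates 1 and 2, and 5325279 and 5015295 tags in hindlimb replicates 1 and 2. Tags with a gene or cluster held 84.3%, 85.2%, 81.3% and 84.6% of these counts. Across 13718 tested genes, Pearson's r of log2 CPM was 0.928 between the forelimb replicates and 0.927 between the hindlimb replicates, against 0.777 to 0.888 between limb types. Genes are not independent replicates in these correlations. The libraries of a limb type were not resamplings of a single library, with a chi-square per degree of freedom of 9.04 for the forelimb pair over 13252 genes and 21.9 for the hindlimb pair over 13557 genes. That they are biological replicates rests on the labels.

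The comparison asked which genes differ between the limb types during limb growth. Transcription factors that distinguish the limbs differed in opposite directions. Pitx1, Tbx4 and Hoxc10 were higher in hindlimb and Tbx5 was higher in forelimb, each by 2.95 or more on the log2 scale. Of 31 tested skeletal muscle genes, 9 were lower in hindlimb, among them Acta1 and Myh8 of the contractile apparatus, and 22 did not pass. As a list they ranked below other genes in hindlimb (camera adjusted p = 0.00302; adjusted p = 0.634 with an estimated correlation). In all, edgeR called 1314 genes higher in hindlimb and 971 higher in forelimb, 16.7% of those tested. Most of these calls were lost with the tag-sequence offset, under which 13 genes were higher in hindlimb and 16 higher in forelimb. Not all of these 29 are sure, since several rest on tags that match several genes. Of the 29, 22 were also called, in the same direction, without the offset. Single libraries moved the count as well: it was 1035 without forelimb replicate 1, 950 without forelimb replicate 2, 1034 without hindlimb replicate 2 and 3900 without hindlimb replicate 1.

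Pitx1, the homeobox gene that specifies hindlimb identity (ENSMUSG00000021506, chromosome 13, 55825051 to 55836192, minus strand, GRCm38), had 2.29 ± 1.48 CPM in forelimb and 279 ± 35.6 CPM in hindlimb (n = 2 each). Its log2 fold change was 6.72 ± 0.47 (SE, edgeR adjusted p = 3.5e-07), and 5.01 with the tag-sequence offset. Tbx4, a T-box factor of the hindlimb (ENSMUSG00000000094, chromosome 11, 85886422 to 85916097, plus strand), had 5.91 ± 3.96 CPM in forelimb and 50.4 ± 10.2 CPM in hindlimb, a log2 fold change of 2.95 ± 0.47 (SE, adjusted p = 0.00101). Hoxc10, a posterior gene of the HoxC cluster (ENSMUSG00000022484, chromosome 15, 102966796 to 102971893, plus strand), had 1.26 ± 0.027 CPM in forelimb and 18.5 ± 1.47 CPM in hindlimb, a log2 fold change of 3.83 ± 0.66 (SE, adjusted p = 0.00168). Tbx5, the T-box factor required for forelimb formation (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219, plus strand), had 16.7 ± 2.49 CPM in forelimb and 1.21 ± 0.443 CPM in hindlimb, a log2 fold change of −3.77 ± 0.69 (SE, adjusted p = 0.00246). All of these genes are protein coding. Tbx4, Hoxc10 and Tbx5 also passed with the tag-sequence offset, at 3.12, 3.69 and −4.17. The low limb type rested on few counts. In forelimb replicates 1 and 2, Hoxc10 had 5 and 2 counts and Pitx1 had 13 and 2. In hindlimb replicates 1 and 2, Tbx5 had 4 and 6. The SD of 0.027 CPM of Hoxc10 therefore does not measure its precision.

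**Figure D1:**
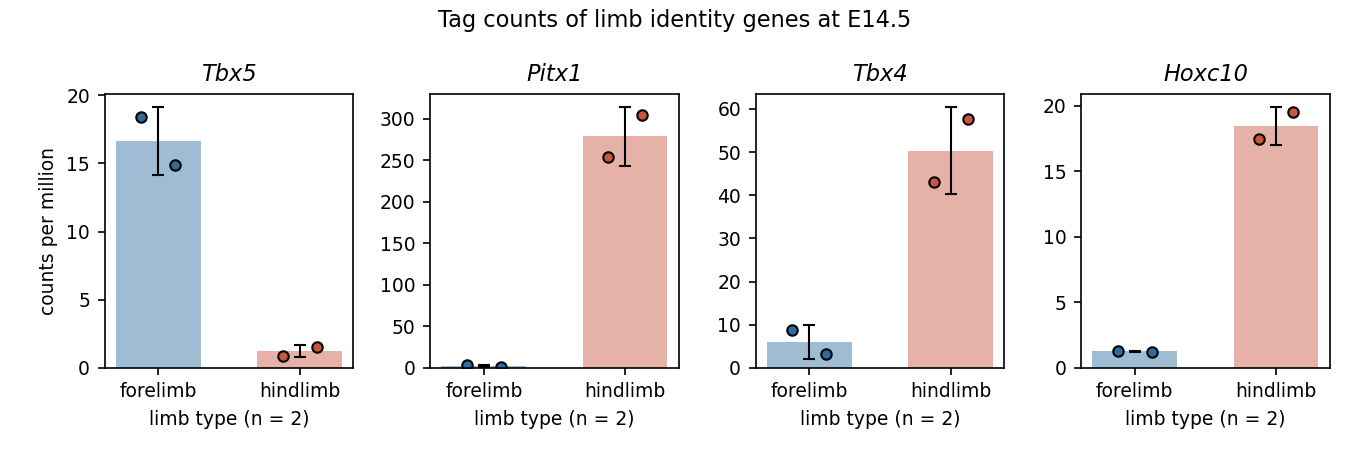
Normalized counts (CPM) of Tbx5, Pitx1, Tbx4 and Hoxc10 in forelimb (blue) and hindlimb (red), each panel on its own linear axis from 0. Points are the 2 libraries of each limb type, bars are their mean and error bars 1 SD. Tbx5 averaged 16.7 CPM in forelimb and 1.21 CPM in hindlimb, and the other genes were higher in both hindlimb libraries than in both forelimb libraries.

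Of the hindlimb identity list, 6 genes were tested and 4 were higher in hindlimb, Pitx1, Tbx4, Hoxc10 and Hoxc9; adjusted over the list alone all 6 were. The median log2 fold change of the list was 3.39, or 2.76 with Hoxc9 at its lower bound. Hoxc9 had no count in forelimb and 3.20 ± 0.22 CPM in hindlimb, at least 5.90-fold higher (edgeR adjusted p = 0.0463), a call that ended with each of the 3 offsets, though the fitted log2 fold change hardly moved (6.06, 6.05 and 6.09, against 6.49), and without forelimb replicate 1, forelimb replicate 2 or hindlimb replicate 2 (6.44, 6.73 and 6.50), and with library totals alone or no low-count filter. The list ranked above other genes in hindlimb (camera adjusted p = 3.5e-05; adjusted p = 0.634 with an estimated correlation, the highest of its alternatives, which began at 5.2e-07). Of the forelimb identity list, Tbx5 alone of 4 tested genes was called, and 3 genes were called adjusted over the list alone; the median log2 fold change was −2.84. Hoxc4, Hoxc5 and Hoxc6, anterior genes of the HoxC cluster, were the members that did not pass over all genes. This list ranked above other genes in forelimb (camera adjusted p = 0.00477; adjusted p = 0.634 with an estimated correlation, with alternatives from 1.5e-05 to 0.634). Its call was lost without forelimb replicate 1 (adjusted p = 0.0516) and without hindlimb replicate 1 (adjusted p = 0.0572).

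Members of the 4 Hox clusters went both ways. In the HoxC cluster, Hoxc10 and Hoxc9 were higher in hindlimb and 5 of the 7 tested genes did not pass; adjusted over the list alone, 4 were higher in hindlimb and 2 in forelimb. The cluster as a whole had a camera adjusted p of 0.551. In the HoxA cluster, with 10 tested genes, Hoxa3, of the anterior part, was higher in hindlimb (log2 fold change 2.46 ± 0.58 SE, adjusted p = 0.00886) and Hoxa11, which patterns the zeugopod, higher in forelimb (−1.46 ± 0.40 SE, adjusted p = 0.0186), the same counts adjusted over the list alone, with a camera adjusted p of 0.766. With the tag-sequence offset Hoxa3 was at 0.81 and Hoxa11 turned to 0.31, neither past the test. In the HoxB cluster Hoxb9 was the 1 called gene of 4, over all genes and adjusted over the list alone, with 0.384 ± 0.543 CPM in forelimb and 7.19 ± 1.21 CPM in hindlimb (log2 fold change 3.74 ± 1.10 SE, adjusted p = 0.0282). That list's median was −0.11, its mean 0.64, and camera placed it toward hindlimb (adjusted p = 0.766). In the HoxD cluster Hoxd11 was higher in forelimb (−1.07 ± 0.35 SE, adjusted p = 0.0458), 1 of 6 tested and 2 adjusted over the list alone, with a camera adjusted p of 0.709. The calls of Hoxb9 and Hoxd11 ended with the tag-sequence offset, at 3.54 and −0.30. Without hindlimb replicate 2 the calls of Hoxa3, Hoxa11 (−1.17), Hoxb9 (3.92) and Hoxd11 (−1.07) ended, and further libraries ended those of the last 3.

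Of 41 tested genes of limb patterning and signalling, 6 were higher in hindlimb and 4 higher in forelimb (6 and 7 adjusted over the list alone; camera adjusted p = 0.325). Among them were Irx5 (2.42 ± 0.43 SE), Prrx2 (2.04 ± 0.38 SE) and Hand2 (1.79 ± 0.40 SE), transcription factors of limb mesenchyme, all higher in hindlimb, and Tbx18 (−2.24 ± 0.46 SE), higher in forelimb. Their adjusted p ran from 0.00204 to 0.00672. These genes stood at 0.72, 0.40, 0.92 and −1.74 with the tag-sequence offset and did not pass. The call of Hand2 also ended without forelimb replicate 2 (1.64) and without hindlimb replicate 2 (0.97). From the last NlaIII site alone the calls of Hand2 (0.35) and Tbx18 (−0.91) ended.

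Skeletal genes also split by direction. Of 21 cartilage genes, 5 were higher in hindlimb and 2 in forelimb, over all genes and adjusted over the list alone (camera adjusted p = 0.720). Col2a1 and Col9a2, collagens of the cartilage matrix, were higher in hindlimb at 1.46 ± 0.35 and 1.75 ± 0.33 (SE), with Col2a1 at 938 ± 227 CPM in forelimb and 2578 ± 1010 CPM in hindlimb. Matn1, a cartilage matrix protein, and Epyc, a proteoglycan of the growth plate, were higher in forelimb at −1.26 ± 0.32 and −1.60 ± 0.42 (SE). The adjusted p of these genes ran from 0.00293 to 0.0159. In hypertrophic cartilage and growth plate, 4 of 18 genes were higher in forelimb (1 gene higher in hindlimb and 4 in forelimb adjusted over the list alone; camera adjusted p = 0.551). They were Ibsp (−1.92 ± 0.32 SE), Spp1 (−1.56 ± 0.33 SE), Col10a1 (−1.79 ± 0.42 SE) and Mef2c (−0.99 ± 0.31 SE), with adjusted p between 0.00131 and 0.035. Ibsp and Spp1, sialoproteins of mineralizing matrix, were with Phex (−1.72 ± 0.37 SE, adjusted p = 0.00578) also the 3 of 16 osteoblast genes higher in forelimb, over all genes and adjusted over the list alone (camera adjusted p = 0.551). Spp1 had 102 ± 4.17 CPM in forelimb and 34.5 ± 2.15 CPM in hindlimb and passed with the tag-sequence offset at −1.60, though not when each gene was read from its most abundant tag (−1.18) or from its last NlaIII site (−1.17). The other cartilage and bone genes named here did not pass with that offset; Col9a2, Col2a1 and Ibsp were then at 0.021, 0.33 and −0.66, while Col10a1 and Epyc kept more of their change, at −1.38 and −0.98. Without forelimb replicate 2 the calls of Col2a1 (1.22), Matn1 (−0.98), Epyc (−0.81), Col10a1 (−1.22) and Mef2c ended. Without forelimb replicate 1 those of Phex (−1.52) and Mef2c (−0.99) ended, and without hindlimb replicate 2 those of Col2a1 and Mef2c (−0.93). From the most abundant tag the calls of Col10a1 (−1.65) and Mef2c (−1.04) ended.

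In the joint interzone list Nog, a BMP antagonist, was the 1 of 16 genes higher in hindlimb (1.64 ± 0.54 SE, adjusted p = 0.0441), a call that ended without any 1 of the 4 libraries (1.47 to 1.79), with DESeq2 (1.62), with library totals alone (1.61) and with thinning to the smallest library (1.33). Adjusted over the list alone 0 of its genes passed edgeR's test, against 8 at an unadjusted p under 0.05, and DESeq2 over all genes called 1, which was not Nog (camera adjusted p = 0.374). Of 17 tendon genes, 1 was higher in hindlimb and 5 in forelimb (2 and 6 adjusted over the list alone; camera adjusted p = 0.272). Scx, the transcription factor of tendon progenitors, had 12.1 ± 5.70 CPM in forelimb and 86.9 ± 25.5 CPM in hindlimb (2.77 ± 0.42 SE, adjusted p = 6.7e-04). Dcn and Fmod, small proteoglycans of tendon matrix, and Egr1 were higher in forelimb at −1.74 ± 0.32, −1.71 ± 0.41 and −1.11 ± 0.32 (SE), with adjusted p of 0.00239, 0.0105 and 0.0256. With the tag-sequence offset Nog was at 0.53, Scx at 0.88, Dcn at −0.52, Fmod at −1.21 and Egr1 at −0.62, and these genes did not pass. Without forelimb replicate 2 the calls of Fmod (−1.38) and Egr1 (−1.01) ended, and that of Egr1 also without forelimb replicate 1 (−1.22) or hindlimb replicate 2 (−1.12). Both calls also ended from the most abundant tag (−1.61 and −1.20), and that of Fmod from the last NlaIII site (−0.70).

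Skeletal muscle genes ranked toward forelimb as a list. Of 31 tested genes, 9 were higher in forelimb and 22 did not pass (11 were higher in forelimb adjusted over the list alone), and 23 had a log2 fold change below 0. The median was −0.74, and camera ranked the list below other genes in hindlimb (adjusted p = 0.00302; adjusted p = 0.634 with an estimated correlation, with alternatives from 1.1e-11 to 0.634). Acta1, skeletal muscle actin, had 1671 ± 437 CPM in forelimb and 535 ± 18.3 CPM in hindlimb (log2 fold change −1.64 ± 0.33 SE, edgeR adjusted p = 0.00347). Myh8, perinatal myosin heavy chain, had 138 ± 7.61 CPM in forelimb and 38.4 ± 5.50 CPM in hindlimb (−1.84 ± 0.33 SE, adjusted p = 0.00218). Tnnc2, fast troponin C, and Neb, nebulin of the thin filament, were at −1.79 ± 0.33 and −1.74 ± 0.33 (SE), with adjusted p of 0.00246 and 0.00294. With the tag-sequence offset the SD across members narrowed from 0.84 to 0.48, but it also narrowed across all tested genes, from 1.16 to 0.74. With that offset 29 of the 31 genes lay below 0, the median was −0.75, and camera called the list (adjusted p = 1.1e-11, or 0.330 with an estimated correlation). Acta1 and Myh8 passed there at −1.20 and −1.42, and Tnnc2 and Neb did not, at −1.07 and −0.60. Tags that match several genes made up 38.2% of the counts of Myh8, so its share among the myosin genes is uncertain.

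**Figure D2:**
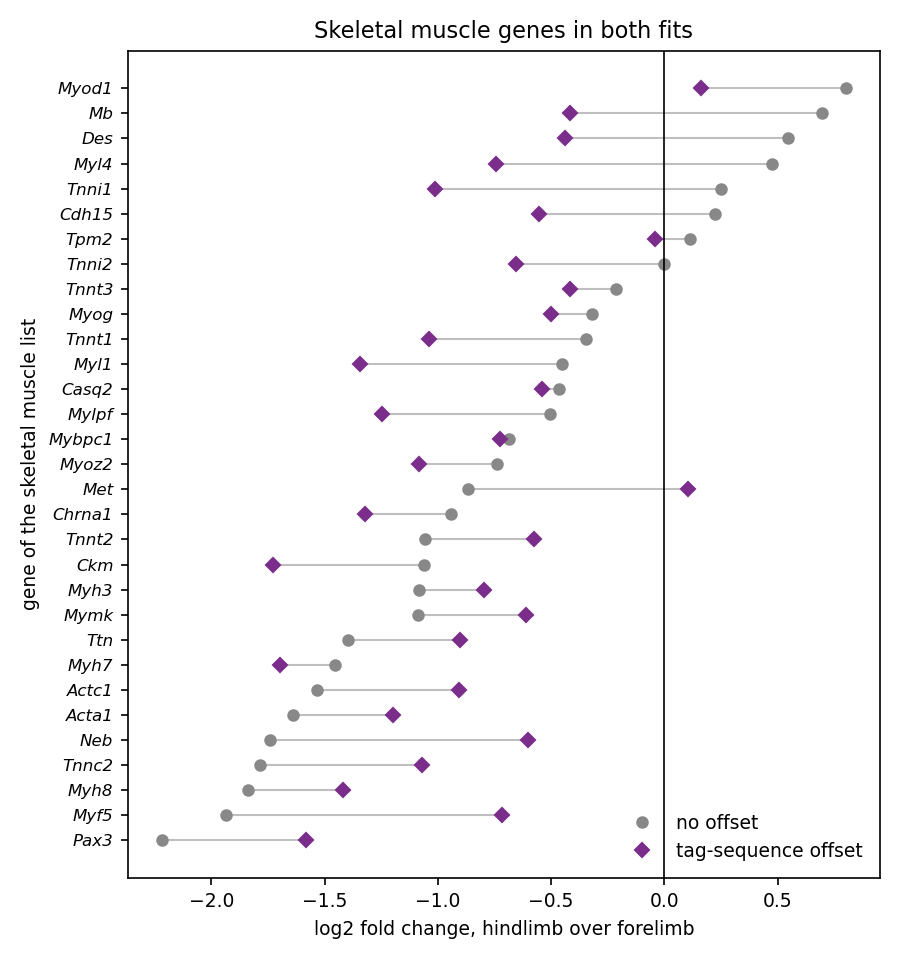
Log2 fold change, hindlimb over forelimb, of the 31 tested genes of the skeletal muscle list, without an offset (grey circles) and with the tag-sequence offset (purple diamonds), joined by a line for each gene. Values left of 0 are higher in forelimb: 23 genes without and 29 genes with the offset.

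Of 30 cell cycle genes, 4 were higher in hindlimb and 6 in forelimb, over all genes and adjusted over the list alone (camera adjusted p = 0.766). Cdc20, an activator of the anaphase-promoting complex, and Tk1, thymidine kinase, were higher in hindlimb at 2.29 ± 0.37 and 1.62 ± 0.37 (SE). Ccne2, a cyclin of the entry into S phase, and Pcna, the replication clamp, were higher in forelimb at −1.49 ± 0.34 and −1.43 ± 0.33 (SE). Their adjusted p ran from 0.00118 to 0.00749. Cdc20, Tk1 and Pcna are uncertain, since 89.6%, 65.2% and 34.1% of their counts came from tags that match several genes; from tags of 1 M21 gene Tk1 was at 0.83 and did not pass. The call of Ccne2 ended from the most abundant tag (−1.14) and from the last NlaIII site (−1.13). Among 24 growth factors and imprinted growth genes, Igf2r, a receptor that clears IGF2, was higher in hindlimb (1.40 ± 0.34 SE, adjusted p = 0.0108) and Plagl1, an imprinted transcription factor, higher in forelimb (−1.18 ± 0.31 SE, adjusted p = 0.0165), the same counts adjusted over the list alone (camera adjusted p = 0.551). None of these named genes passed with the tag-sequence offset, and Plagl1 turned to 0.034. Without forelimb replicate 2 the calls of Tk1 (1.30), Pcna (−1.31), Igf2r (1.18) and Plagl1 (−1.22) ended, and without forelimb replicate 1 those of Ccne2 (−1.44) and Plagl1 (−1.14). The call of Plagl1 also ended without hindlimb replicate 2.

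Markers of other cell types went in both directions. Of 9 erythroid genes, Hba-a2, an adult alpha globin, was higher in hindlimb (2.72 ± 0.33 SE, adjusted p = 1.5e-04), while Hbb-bs, an adult beta globin, and Car2, carbonic anhydrase, were higher in forelimb at −1.03 ± 0.32 and −2.08 ± 0.47 (SE, adjusted p = 0.0362 and 0.00751). Adjusted over the list alone, 2 were higher in each limb type; the median was −0.57, the mean 0.16 and the camera adjusted p 0.882. Tags that match several genes held 73.3% of the counts of Hba-a2 and 98.5% of those of Hbb-bs. Of 15 endothelial genes, Pecam1 and Cldn5, proteins of endothelial junctions, were higher in hindlimb at 2.08 ± 0.37 and 2.32 ± 0.50 (SE), and Cdh5, another junction protein, was higher in forelimb at −1.16 ± 0.35 (SE), with adjusted p from 0.00201 to 0.0315, the same counts adjusted over the list alone (camera adjusted p = 0.766). Of 18 epidermal genes, Jup (2.57 ± 0.38 SE), Krt14 (1.04 ± 0.33 SE) and Krt1 (0.97 ± 0.32 SE) were higher in hindlimb, while Krt10 (−1.26 ± 0.32 SE) and, named after its value was seen, the transcription factor Trp63 (−1.15) were higher in forelimb (4 and 2 adjusted over the list alone). The adjusted p of Jup, Krt14, Krt1 and Krt10 ran from 6.0e-04 to 0.0445; the median of the list was −0.020, its mean 0.16 and the camera adjusted p 0.766. Krt14 and Krt1 are keratins of the basal and the differentiating epidermis. None of these genes passed with the tag-sequence offset; Hba-a2 was at 0.78 and Krt14 turned to −0.27. Without forelimb replicate 1 the calls of Hbb-bs (−0.86), Car2 (−1.74), Cdh5 (−0.82), Krt14 (1.04) and Krt1 (0.86) ended, and those of all of these except Car2 also ended without hindlimb replicate 2; those of Cdh5 (−1.42), Krt14 (1.03), Krt1 (1.08) and Krt10 (−1.06) ended without forelimb replicate 2, and that of Hbb-bs also without hindlimb replicate 1 (−0.93). The call of Krt1 (0.92) ended with library totals alone.

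Of 12 macrophage genes, C1qa (−1.75 ± 0.48 SE, adjusted p = 0.02) and Lyz2 (−1.59 ± 0.54 SE, adjusted p = 0.0497), a complement component and lysozyme, were higher in forelimb, also adjusted over the list alone (camera adjusted p = 0.432); 92.8% of the counts of Lyz2 came from tags that match several genes, and those of C1qa were not mostly in tags that match it in M21. Of 12 genes of Schwann cells and neural crest, 0 passed edgeR's test over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 with DESeq2 (camera adjusted p = 0.551), and the 2 most abundant, Ngfr and Fabp7, stood at 0.47 and −1.20. These depended on the setting: Ngfr passed as higher in hindlimb from the last NlaIII site (adjusted p = 0.00221), and was at −0.69 from its most abundant tag and −0.23 with the GC offset. Fabp7 passed without hindlimb replicate 1 (−1.38), from the last NlaIII site (−1.46), with Ensembl genes alone (−1.21) and with thinning (−1.42). Of 6 neuronal genes, Dcx (−1.61 ± 0.37 SE, adjusted p = 0.00738) and Stmn2 (−1.57 ± 0.44 SE, adjusted p = 0.0227), a pair of microtubule-binding proteins of young neurons, were higher in forelimb (3 adjusted over the list alone; camera adjusted p = 0.263). In the list of mature adipose and smooth muscle, with 8 tested genes, Cspg4, a proteoglycan of pericytes, was higher in hindlimb (42.9 ± 3.49 CPM in forelimb and 150.3 ± 45.95 CPM in hindlimb, adjusted p = 0.00299) and Acta2, smooth muscle actin, higher in forelimb (−1.41 ± 0.35 SE, adjusted p = 0.0117). Pparg, the regulator of fat cell formation, had 4.08 ± 2.14 CPM in forelimb and no count in hindlimb, at least 9.67-fold lower (adjusted p = 0.0282). Adjusted over the list alone 1 was higher in hindlimb and 3 in forelimb (camera adjusted p = 0.551). Of 13 immediate early and stress genes, Junb was higher in hindlimb (1.68 ± 0.51 SE, adjusted p = 0.0324), and Egr1 and the heat shock gene Hsph1 (−1.28 ± 0.42 SE, adjusted p = 0.0435) were higher in forelimb; 2 passed in each direction adjusted over the list alone, the median was −0.10, the mean 0.024 and the camera adjusted p 0.766. Of 5 sex-linked genes, 0 passed edgeR's test over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 with DESeq2 (camera adjusted p = 0.766). Ddx3y, on the Y chromosome, had 74.9 ± 44.4 CPM in forelimb and 91.5 ± 6.79 CPM in hindlimb, and Xist, transcribed from the inactive X, had 67.8 ± 9.63 CPM and 34.4 ± 3.73 CPM. Both were counted in all 4 libraries. A difference in the share of male embryos would move Xist and the Y genes in opposite directions, so camera, which asks for 1 direction, is poorly suited to show it. Without an offset 3 genes of the list lay above 0 and 2 below, and with the tag-sequence offset 4 lay above and Xist below. Whether the limb types differed in sex was not tested. Xist passed with the tag-sequence offset, at −1.43, and the other genes named in this paragraph did not. C1qa went from −1.75 to −1.13 with it, Stmn2 from −1.57 to −0.95 and Dcx from −1.61 to −1. Pparg was at −5.92, against −6.79 without the offset, but with no count in hindlimb the size of its fitted value is uncertain. Without forelimb replicate 1 the calls of C1qa (−1.62), Lyz2 (−1.34), Stmn2 (−1.71), Junb and Hsph1 (−1.57) ended, those of all of these except C1qa also without forelimb replicate 2 or hindlimb replicate 2. The call of Acta2 (−1.20) ended without forelimb replicate 2, and that of Pparg without hindlimb replicate 1 (−6.65) or hindlimb replicate 2 (−6.72). Calls also ended for Lyz2 and Junb with DESeq2 and with thinning, for Lyz2 (−1.65) and Stmn2 (−1.16) from the most abundant tag, for Stmn2 from the last NlaIII site (−2.11), and for Lyz2 and Hsph1 with library totals alone.

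The largest fold changes past the threshold were mostly of genes with no count in one limb type. Among the 8 largest toward hindlimb, Pitx1 was the 1 gene counted in forelimb. Mm_481703 was at least 16.6-fold and Mm_42070 at least 13.8-fold higher in hindlimb, C530025M09Rik, whose counts came mostly from tags that match Syndig1 in M21, at least 9.61-fold, Gm11491 at least 6.55-fold and Dnajb3, a chaperone gene, at least 6.33-fold. The 8 largest toward forelimb all lacked counts in hindlimb. Mm_372548 was at least 17.3-fold lower in hindlimb, Plb1, phospholipase B, at least 12.7-fold, Mm_414003 and the profilin gene Pfn4 at least 12.2-fold each, and Ms4a4c at least 11.2-fold. Egf, epidermal growth factor, had 4.57 ± 2.95 CPM in forelimb and none in hindlimb, at least 15.3-fold, but from tags of 1 M21 gene its log2 fold change was −3.18 and did not pass. Apart from Pitx1, the 8 genes of each direction averaged under 10 CPM in the limb type that had them, with adjusted p from 0.00466 (Mm_481703) to 0.0463 (Hoxc9). Their calls, except that of Pitx1, ended with the tag-sequence offset, but the fitted log2 fold changes stayed large, at 6.09 (Hoxc9) to 7.28 (Mm_481703) toward hindlimb, against 6.49 to 8.02 without it, and at −6.24 (Mm_446194) to −6.57 (Mm_372548) toward forelimb, against −6.84 to −7.33. The loss therefore does not show that bases of the tags account for these differences. With no count in 1 limb type the size of a fitted value is uncertain, so it does not show the opposite either. Except for Mm_372548 and Pitx1, each call also ended without at least 1 library, again with large fitted values.

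The base composition of the tags separated the limb types. The count-weighted GC content of assigned tags, adapter tags left out, was 40.5% and 40.2% in forelimb replicates 1 and 2, and 46.2% and 50.4% in hindlimb replicates 1 and 2. Across genes, which are not independent, Spearman's rho between the log2 fold change and the GC percent of a gene's tags was 0.664. Of 2674 genes with tags of 55% GC or more, 948 were called higher in hindlimb and 4 higher in forelimb; of 2833 genes below 35%, 6 were higher in hindlimb and 558 higher in forelimb. The relation held between tags of the same gene, where hindlimb over forelimb rose by 0.64 on the log2 scale per 10 points of GC (SE 0.0073). By position, counted from 1 at the base after CATG, C instead of A at position 1 went with 1.82 more, and G with 1.47 more. At position 2 the difference was 1.23 for C and −0.52 for G. Over positions 3 to 17 it averaged 0.35 for C, 0.37 for G and 0.032 for T. Base and position explained 54.5% of the variance between tags of the same gene. With the GC offset edgeR called 398 genes higher in hindlimb and 429 higher in forelimb. Spearman's rho with the GC percent was then 0.042, and it was 0.180 with the tag-sequence offset. The 2 hindlimb libraries also differed from each other. Per 10 points of GC, log2 CPM deviated from the mean of the libraries by 0.13 and 0.47 in hindlimb replicates 1 and 2. It deviated by −0.27 and −0.32 in forelimb replicates 1 and 2. Part of the trend thus varied between libraries of 1 limb type. For the part between limb types, limb type and library preparation cannot be told apart, since the compositions did not overlap and no batch is given.

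**Figure D3:**
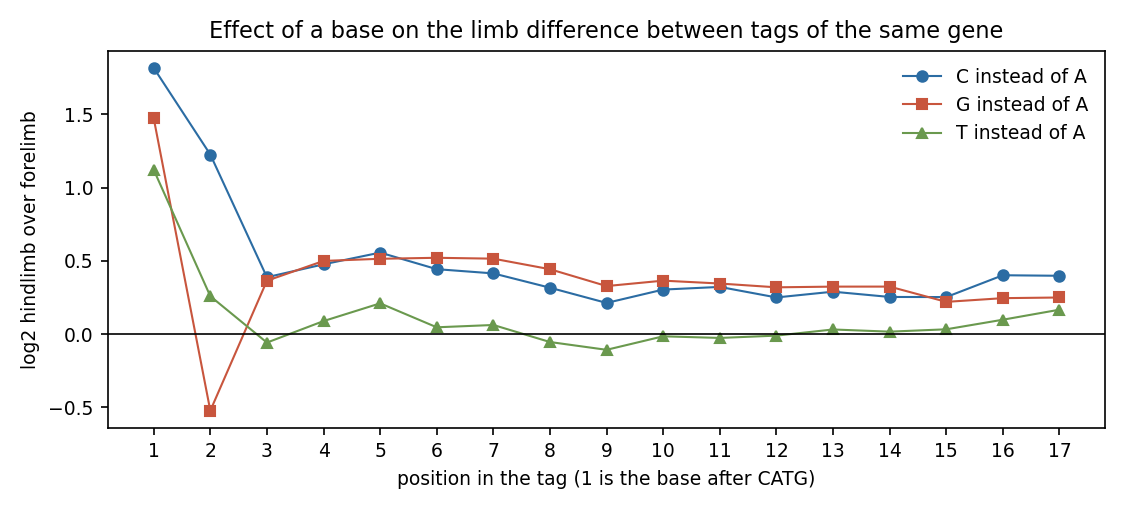
Effect of the base at each of the 17 positions of a tag on log2 hindlimb over forelimb, relative to A, from differences between tags of the same gene. The effects of C and G were largest at position 1 (1.82 and 1.47), that of G was −0.52 at position 2, and effects of C and G stayed above 0 at the later positions.

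Among counts in tags that match 1 M21 gene, the last NlaIII site held 56.9% and 51.8% in forelimb replicates 1 and 2. In hindlimb replicates 1 and 2 it held 55.8% and 60.7%. A change in the ratio of tags therefore need not be a change of transcript end. Tag usage was tested in 8694 genes with 33954 tags, and edgeR called 924 genes (10.6%). The smallest adjusted p were those of Sparc (8.7e-10), an extracellular matrix protein of bone and connective tissue, Mlec (5.3e-07), a lectin of the endoplasmic reticulum, the ribosomal protein gene Rpl12 (7.9e-07), Cnn3 (7.2e-06), a calponin, and Morf4l1 (1.1e-05), a chromatin protein. In Sparc the tag CAAACTCTCACAGCAAT had 744 and 391 CPM in forelimb replicates 1 and 2, against 0 and 0.874 CPM in hindlimb replicates 1 and 2. It is the reference tag next to the last NlaIII site of Sparc, in the 3' UTR (chromosome 11, 55394552 to 55394568, minus strand, GRCm38). Another tag of Sparc, with 64.7% GC, went the other way. It had 2.08 and 0 CPM in forelimb replicates 1 and 2, and 194 and 240 CPM in hindlimb replicates 1 and 2. It was higher in hindlimb than the other tags of the gene by a log2 fold change of 5.01. Sparc as a whole did not differ (log2 fold change 0.04 ± 0.31 SE, adjusted p = 0.949). In Mlec the tag CCCCACCCCACTCCCAC, with 76.5% GC, had 7.73 and 5.62 CPM in the forelimb replicates and 254 and 418 CPM in the hindlimb replicates. In Rpl12 the tag CCGCCCAAGTTCGACCC, with 70.6% GC, had 24.1 and 16.9 CPM in forelimb and 453 and 757 CPM in hindlimb. In Cnn3 the tag ATATATTTGAAGCAAAC, with 23.5% GC, was lower in hindlimb than the other tags of the gene by a log2 fold change of −3.07. The number of calls rested on single libraries: it was 12 without forelimb replicate 1, 26 without forelimb replicate 2, 144 without hindlimb replicate 2 and 2144 without hindlimb replicate 1. With limma-voom, 2045 genes were called without and 19 with the tag-sequence model; of the 5 genes, Cnn3 then passed (adjusted p = 1.5e-05, with alternatives from 4.1e-10 to 0.036), and Sparc (0.102), Mlec (0.178), Rpl12 (0.187) and Morf4l1 (0.589) did not. From the top 2 tags of each gene alone, Sparc and Morf4l1 did not pass. In both genes the tag with the smallest p is not among those 2, so this setting could not test it. Morf4l1 also did not pass without forelimb replicate 1.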

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

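The measures in this part were chosen after the data had been seen. Tags that hold 10 or more bases of the sequencing adapter stood out in data outside the comparison, with 1.85% and 0.69% of the counts in forelimb replicates 1 and 2 and 2.46% and 1.26% in hindlimb replicates 1 and 2. Tags of ribosomal RNA copies, in either strand, took 0.757% and 0.571% of the counts in forelimb and 1.70% and 2.19% in hindlimb. A set of 644 tags was nearly confined to hindlimb replicate 1, with 76754 counts there, 1.44% of that library, and 376 counts in the other 3 libraries together; 642 of these tags matched no M21 transcript in either strand. No explanation was tested for these values.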

How the results depend on the processing

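Results with the GC, GC and first-base, and tag-sequence offsets, other tag sets, thinning, the crossed block and limma-voom were chosen after the data had been seen; the other alternatives were fixed beforehand. Pitx1, Tbx4, Hoxc10, Acta1 and Myh8 kept their direction and their call in all 20 settings run for them, and Tbx5 in all 19. With other size factors, library totals alone, no filter or a stricter one, DESeq2, the most abundant tag, no haemoglobin genes, no adapter tags, tags of 1 gene, the last NlaIII site, Ensembl genes or thinning, the called genes numbered 2076 to 2933 in all. The replicate block, whose numbers do not pair the samples by any label, gave 2151 genes, 3 lists and 159 genes of differing tag usage. It ended the calls of 11 followed genes with their direction kept. These were Gm11491 (6.51), Dnajb3 (6.52), Hoxc9 (6.52), Hoxd11 (−1.025), Mef2c (−0.99), Nog (1.64), Hbb-bs (−1.03), Krt14 (0.99), Krt1 (0.95), Lyz2 (−1.62) and Pparg (−6.79). Crossing the numbers gave 1684 genes higher in hindlimb and 1486 higher in forelimb.

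Genes higher in hindlimb and in forelimb numbered 398 and 429 with the GC offset, 312 and 235 with the GC and first-base offset, and 13 and 16 with the tag-sequence offset. At an adjusted p under 0.1, 1634 were higher in forelimb; under 0.01 the numbers were 555 and 238. Leaving out 1 library gave 583 to 1899 genes higher in hindlimb and 367 to 2001 higher in forelimb, and 12 to 2144 genes of differing tag usage. The lone library of a limb type is then assumed to vary like the other limb type. Forelimb replicate 2 held 1829647 counts, which limits what can be told of genes at a few CPM.

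Of the 24 lists, camera called 3. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05. The correlations estimated for hindlimb identity, forelimb identity and skeletal muscle were 0.043, −0.154 and 0.019, against the preset 0.01. Since this setting also drops to 2 degrees of freedom, a call lost in it counts neither for nor against a list. Fry called 6 lists by direction and 22 in either direction. With the GC offset 5 lists were called, tendon and macrophage besides the others, and 0 with an estimated correlation beside it. With the tag-sequence offset 3 were called, and 0 with an estimated correlation. Tag usage differed in 526 genes from the top 2 tags of each gene, 2045 with limma-voom, 1430 with limma-voom and the GC offset, and 19 with the tag-sequence model.

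Among 76 genes followed across settings, calls ended with the direction kept for 41 with the GC offset, 48 with the GC and first-base offset and 62 with the tag-sequence offset, and for 22, 36, 4 and 29 without forelimb replicate 1, forelimb replicate 2, hindlimb replicate 1 and hindlimb replicate 2. In addition directions reversed, and calls ended, with the GC and first-base offset for Hoxa3 (−0.079), Igf2r (−0.15), Krt14 (−0.22) and Cspg4 (−0.10), and with the tag-sequence offset for Hoxa11 (0.31), Krt14 (−0.27) and Plagl1 (0.034). These shifts follow from the base terms subtracted; for the other changes the cause was not tested.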

Other observations

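The genes in the next paragraphs were chosen after their values were seen, as were all tests below except those of the GC offset, of depth, of the 3' end and of erythroid genes other than globins, whose predictions came first.

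With the tag-sequence offset, several muscle genes outside the named ones were lower in hindlimb. Ldb3, a protein of the Z disc, had 83.3 ± 8.90 CPM in forelimb and 19.6 ± 0.444 CPM in hindlimb (n = 2 each; log2 fold change −2.09, −1.84 with the offset). Sln, a regulator of the muscle calcium pump, had 126 ± 12.7 CPM and 47.5 ± 0.529 CPM (−1.41, −1.43 with the offset). The myosin light chain genes Myl1 and Mylpf passed with the tag-sequence offset, at −1.34 and −1.25, and not without an offset, at −0.45 and −0.51. Mylpf also passed with the GC offset (−1.11) and with the GC and first-base offset (−1.38). Myl1 did not pass with these, at −0.068 and −0.20, so its call rests on 1 of the 3 offsets. Ccn3, a secreted matricellular protein, was lower in hindlimb at −2.41 (−1.64 with the offset), Tmem14c at −3.61 (−3.14) and the keratin gene Krt84 at −3.91 (−3.51). Higher in hindlimb with the offset were Sfrp2, a secreted inhibitor of Wnt signalling of the joint interzone list (1.33, against 0.80 without it, where it did not pass), and Cmtm3 (1.72, and 1.04 without it).

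Hoxa11 stood at −1.46 without an offset, −0.55 with the GC offset and 0.31 with the tag-sequence offset, while Hoxa11os, the transcript antisense to it, stood at 2.67, 1.59 and 1.29. With the tag-sequence offset neither passed, and 25.3% of the counts of Hoxa11os came from tags that match several genes. The 5 globin genes had a median log2 fold change of −0.72 without an offset, −0.71 with the GC offset and −0.31 with the tag-sequence offset, and the 4 other erythroid genes one of 0.12, 0.24 and 0.30.

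The first pattern weighed is that 2285 genes differed between the limbs. The tables argue against the lower depth of forelimb replicate 2, since 2457 genes were called with every library thinned to the smallest, and against tags away from the 3' end, since 22.5% of tested genes were called from the last NlaIII site alone, against 16.7%. With the GC offset 827 genes were called, and with the tag-sequence offset 29, with 1424 at an unadjusted p under 0.05, so bases of the tags are a candidate explanation for most calls. The fitted offset may also remove real differences, and the simulation of it, with 83 of 100 genes changed by 4-fold recovered, used its own effects. Base composition also differed between the 2 hindlimb libraries (46.2% and 50.4% GC), which limb type alone does not account for. Whether its difference between limb types came from limb type or from library preparation cannot be told apart, since the limb types did not overlap in it. Differences between the limbs stay open for the genes that lost their call.

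The second pattern is that skeletal muscle genes ranked lower in hindlimb as a list (camera adjusted p = 0.00302; adjusted p = 0.634 with an estimated correlation, and 0.330 with that and the tag-sequence offset). Bases of the tags do not account for its median, which was −0.75 with the tag-sequence offset, against −0.74 without it, although of its 9 called genes Acta1 and Myh8 alone passed with the offset. A lower share of muscle cells of every stage remains open: with the offset the 19 sarcomere genes averaged −0.92 and the 5 genes of regulators and progenitors −0.51 (2-sided exact permutation p = 0.0889), a grouping made after the values were seen. The groups hold 24 of the 31 tested genes. That test permutes genes as if independent, though all rest on the same 4 libraries, so its p does not measure variation between samples. A later stage of muscle differentiation in forelimb, or another difference between the limb types, may also underlie it and was not tested apart.

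The third pattern is the Sparc tag nearly confined to forelimb, which differs by A15G from the other abundant tag of Sparc, CAAACTCTCACAGCGAT (positions from 1 after CATG, reference base first). Its share of the pair was 23.6% (Wilson 95% interval 22.8% to 24.4%) of 10618 counts and 12.5% (11.5% to 13.5%) of 4461 in forelimb replicates 1 and 2, against 0 of 10578 in hindlimb replicate 1, with a Wilson upper limit of 0.0363%, and 3 of 12260 in hindlimb replicate 2 (0.0083% to 0.0719%). Sequencing error would give like shares, but the lowest forelimb bound, 11.5%, lay above the hindlimb bounds, and the lower bound of the log2 odds ratio, 9.37, lay above the 0.22 that the fit of base and position alone gives for this substitution. A base variant that differs between the embryos sampled stays open. Of 15 other pairs 1 base apart that keep the GC percent, 5 differed between the 2 libraries in each limb type. Control pairs were 2 tags of 1 gene, from any gene, that are 2 or more bases apart. Of 460 such pairs 142 differed in forelimb and 177 in hindlimb, 30.9% and 38.5% (one-sided Fisher's exact p of the difference, 0.518 and 0.745). Control pairs can share a tag, so they are not independent as that test assumes. Both of their tags match M21, while 1 tag of each pair 1 base apart does not. That test left out pairs that change GC, as the Sparc pair does. Among those, picked from the 64 pairs after its values were seen, Srp14 C7T went the other way. Its tag with T held 0% of the pair in both forelimb replicates, and 15.4% and 12.1% in hindlimb replicates 1 and 2. An effect of limb type itself stays open too and was not tested. The Sparc tag with 64.7% GC, nearly confined to hindlimb, is not part of the Sparc pair and was left out of these tests.

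Over 56 tag pairs 1 base apart, in 53 genes, the mean difference in share was 15.3 points between limb types and 10.9 points within them, larger between in 31 pairs. Over the 15 pairs that keep the GC percent it was 13.5 and 11.1 points, larger between in 8. A sign-flip test was run on these means, but it takes the pairs as independent while all rest on the same 4 libraries, so its p is not relied on. The criteria for pairs were changed once after a first look at the data, and the Sparc pair was the 10th of 64 by the difference of pooled shares.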
